A study of Homo sapiens with 6 samples.

How the data were processed

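RNA from 6 samples of SUM1315 cells was sequenced, 3 labelled normoxia (21% oxygen) and 3 labelled hypoxia (1% oxygen for 24 h). Per the labels' protocols, RNA was isolated with a column kit and 500 ng of total RNA went into libraries made with a kit that does not mark strand. Per the submitters' processing notes, the tools named are Trimmomatic, HISAT2, SAMtools and Partek and the builds are GRCh38 and hg38, with no version. The annotation release, the strand setting of the counting and the selection of RNA are not given in the sources used here.

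The authors deposited 1 table of RPKM values (reads scaled by transcript length and library depth) for 165956 Ensembl transcripts in 6 columns, each matched to its sample by the label. The unit is not written in the table and was inferred from the values. Multiplied by transcript length, low values of genes with 1 transcript piled up at whole multiples of one step per library, 76.8% to 78.5% of them within 0.1 of a whole multiple up to 20. The step gives 44.0 to 50.9 M reads per library. Most values are estimates that split reads between transcripts, so they are not whole reads. One read in a transcript of 2 kb is worth 0.00982 to 0.0114 RPKM. Depth limits precision only for weakly expressed genes, and counting error is the only error this covers.

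The design fixed before the data were examined assumed counts. The table held RPKM instead, so the test set for normalized values was used: limma with a mean-variance trend on log2(RPKM + 1), for genes with more than 1 RPKM in at least 3 libraries, comparing groups without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Transcripts were joined by identifier to GENCODE 29, which matched 140004 (84.4%), and RPKM was summed over 26409 genes. The 25952 transcripts outside that release hold 3.44% to 3.68% of the RPKM and were left out of gene values. Coordinates are from GENCODE 29 on GRCh38, and symbols from a table of current gene names. Summing RPKM over transcripts weights short transcripts more than a read count would. Genes that overlap or share exons cannot be separated with certainty; among named genes this includes MAF1, POLR3K, IDH3A, SUCLA2, NBN, RPS27L, PDCD4 and HSP90B1 besides those marked in the text.

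Before the data were examined, 29 gene lists and 5 lists of cell type markers were fixed. Lists with at least 5 tested members (28) were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the 28 lists. Named genes were chosen by a rule fixed at the same time: 13 genes whatever their values; the 10 largest and 10 smallest log2 fold changes among genes with adjusted p under 0.05, no overlap between groups and a mean of at least 5, applied to RPKM in place of scaled counts (CPM), without pseudogenes; and up to 2 raised and 2 lowered members per list. Levels of lists per library were compared by exact permutation tests.

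Replicates were compared before averaging. Over genes with a mean of at least 50 estimated reads, the mean chi-square per gene between replicates was 6.69 or more, so no libraries agreed within counting noise. The fit was tested on simulated data for hypoxia against normoxia with 11884 genes. Of 50 genes each changed by log2 1 and -1, 100% were recovered in both directions. Of 50 each changed by 0.5 and -0.5, 96% were recovered in both directions, and 5.77% of calls were false. The simulated noise was independent between genes with the same SD in both groups. The real spread was unequal (median SD 0.061 in normoxia, 0.111 in hypoxia), so the share of false calls may differ in the real comparison.

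Alternatives were median-of-ratios and upper-quartile scaling, no filter, a filter at 5 RPKM, a pseudocount of 0.1, the replicate number as a block, leaving out each library, a test against a 1.5-fold change, and camera with an estimated correlation or on ranks, and fry. Chosen after seeing the data were libraries rescaled to equal sums, limma-voom on reads estimated from the steps, removal per library of loess trends (span 0.5) on GC content, length or both, and protein-coding transcripts only. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.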

Results

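Messenger RNA was measured by RNA sequencing in SUM1315, an established cell line from a triple-negative breast cancer, which lacks the receptors that guide hormone or HER2-directed treatment. Cells were kept for 24 h in air with 21% oxygen (normoxia, 3 libraries) or in a sealed chamber with 1% oxygen (hypoxia, 3 libraries). The study asked how low oxygen affects ribosome and ribosomal RNA production and how the oxygen-sensing factor HIF1A takes part. The deposited values are RPKM per transcript, and the depth recovered from their smallest steps was 50.5 to 50.9 M reads in the normoxic and 44.0 to 50.7 M in the hypoxic libraries. Transcript values were summed per gene, and 11884 genes with more than 1 RPKM in at least 3 libraries were tested. Values with ± are means with the SD over 3 libraries, in RPKM, and log2 fold changes are hypoxia against normoxia on the log2(RPKM + 1) scale, which understates changes of weakly expressed genes. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

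In hypoxia 1478 genes were raised and 2901 lowered at an adjusted p under 0.05 (limma, Benjamini-Hochberg). The median log2 fold change of all tested genes was -0.085, so a list median near that value is typical of all genes. The increases were larger than the decreases: 108 genes rose at least 2-fold, and none fell that far at the same threshold. On a 1.5-fold limit the estimates counted 361 raised and 64 lowered genes, and limma's test against a 1.5-fold change called 113 raised and 0 lowered genes. The groups did not overlap for 6175 genes, 52.0% of those tested, where chance gives 10%. The first principal component carried 71.0% of the variance and separated the groups, and replicates correlated at 0.997 to 0.998 in normoxia and 0.993 to 0.995 in hypoxia. The split between directions depended on scaling: lowered genes were 66.2% of the calls with RPKM as deposited (1478 raised, 2901 lowered), 41.3% with median-of-ratios scaling (2021 raised, 1422 lowered), 42.7% with upper-quartile scaling (1971 raised, 1467 lowered) and 78.1% with libraries rescaled to equal sums (1182 raised, 4221 lowered). Without normoxia replicate 1, 2 or 3, genes changed in hypoxia numbered 2822, 2728 and 2549, with 1754, 1621 and 1522 lowered genes.

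Genes known as HIF targets rose nearly as a whole. Of 52 tested members of the list fixed beforehand, 51 were raised and 1 was lowered, the same numbers when adjusted over the list alone, and the median log2 fold change was 1.26 (camera, adjusted p = 1.76e-57; adjusted p = 0.0215 with an estimated correlation). The long noncoding RNA MIR210HG, host of the hypoxia microRNA miR-210, went from 0.253 ± 0.254 to 10.1 ± 2.29 RPKM. DDIT4, an inhibitor of mTORC1 signalling (chromosome 10, 72273920 to 72276036, GRCh38), rose from 31.6 ± 4.40 to 263 ± 17.4, a log2 fold change of 3.02 (SE 0.09, adjusted p = 2.09e-09). DDIT4-AS1 lies wholly within DDIT4 on the other strand (72274915 to 72275980). Its log2 fold change of 3.17 is no measure of its own, since the libraries did not mark strand, and part of the DDIT4 value may likewise come from it. The lowered member was the transferrin receptor TFRC, with a log2 fold change of -0.41 (adjusted p = 0.00243). VEGFA, the main angiogenic growth factor, rose from 10.1 ± 0.428 to 22.2 ± 2.26 (log2 fold change 1.07, SE 0.08, adjusted p = 5.57e-06). CA9, a carbonic anhydrase often used as a hypoxia marker, was near the detection floor: it was listed at 0 in all normoxic libraries and at 0.0639, 0 and 0.0441 RPKM in the hypoxic libraries, about 5.23, 0 and 3.14 estimated reads, and was not tested.

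Glycolysis genes rose with them. Of 20 enzymes and transporters, 19 were raised and 0 lowered, likewise adjusted over the list alone, with a median log2 fold change of 0.97 (camera, adjusted p = 2.12e-27; adjusted p = 0.108 with an estimated correlation). The lactate exporter SLC16A3 (ENSG00000141526, chromosome 17, 82228397 to 82261129) showed the largest increase of all tested genes, from 0.638 ± 0.132 to 68.1 ± 10.8 RPKM (log2 fold change 5.39, SE 0.11, adjusted p = 2.84e-10), and overlaps CSNK1D on the other strand, so that reads can be shared. The glucose transporter SLC2A1 (chromosome 1, 42925375 to 42959176) rose from 5.49 ± 0.220 to 46.9 ± 6.56. Among the 10 largest increases of well-expressed genes were also DEPP1, an autophagy-associated protein (2.51 ± 0.444 to 74.0 ± 7.33), ANGPTL4, an inhibitor of lipoprotein lipase (11.1 ± 0.890 to 91.5 ± 11.4), PFKFB4, which makes the activator of phosphofructokinase (5.86 ± 0.121 to 42.9 ± 3.82), BNIP3, a mitophagy receptor (28.7 ± 1.66 to 162 ± 8.54), and ANKRD37 (1.02 ± 0.210 to 9.95 ± 1.06).

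**Figure D1:**
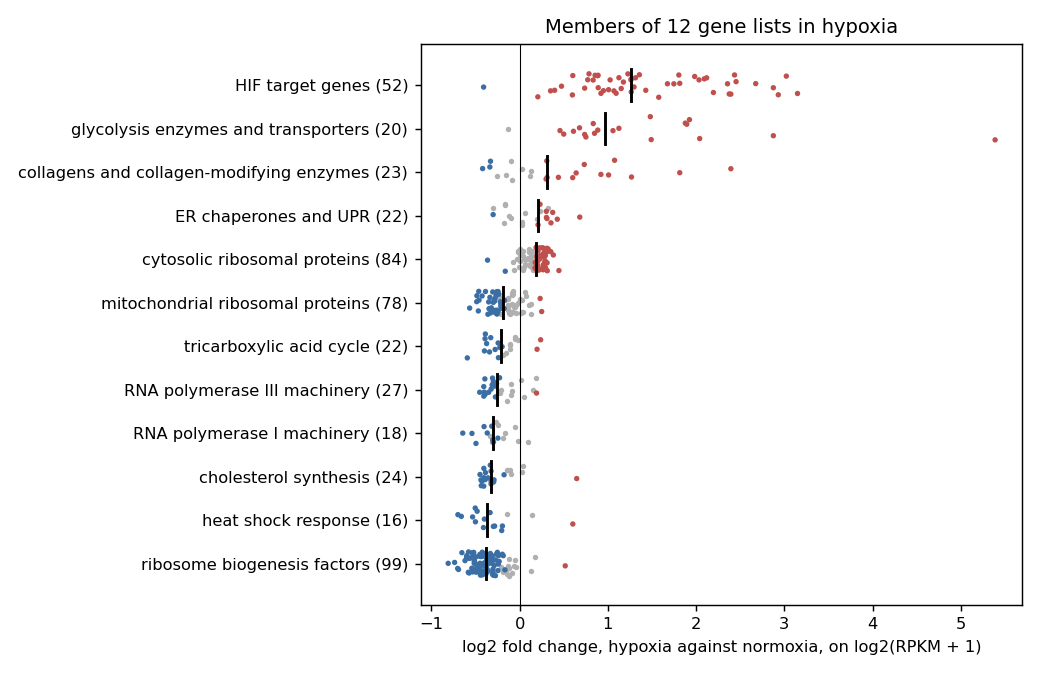
Log2 fold change of each tested member of 12 gene lists (points; number tested in brackets), hypoxia against normoxia on the log2(RPKM + 1) scale; red and blue points passed an adjusted p of 0.05, grey did not, and black bars are list medians. The median is 1.26 for HIF targets, 0.18 for cytosolic ribosomal proteins and -0.39 for ribosome biogenesis factors.

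Ribosome biogenesis factors, the proteins that process ribosomal RNA and assemble ribosomal subunits in the nucleolus, were mostly lower in hypoxia. Of 99 members, 81 were lowered and 1 raised (86 and 2 adjusted over the list alone), with a median log2 fold change of -0.39 (camera, adjusted p = 3.33e-16; adjusted p = 0.108 with an estimated correlation). The small-subunit factor PNO1 (chromosome 2, 68157844 to 68176238) fell to 7.53 ± 0.217 RPKM (log2 fold change -0.81, SE 0.07, adjusted p = 1.66e-05), and WDR3 (chromosome 1, 117929720 to 117966542), part of the small-subunit processome, fell from 52.3 ± 2.07 to 31.1 ± 4.27. The raised member was PPAN, from 42.9 ± 0.570 to 62.0 ± 4.19, a gene that shares reads with the readthrough gene PPAN-P2RY11. The abundant nucleolar proteins chosen beforehand did not move together. Fibrillarin (FBL), the ribosomal RNA methyltransferase, was at 337 ± 7.89 and 380 ± 25.9 (adjusted p = 0.0510), and passed the threshold with median-of-ratios scaling. Nucleolin (NCL) fell from 117 ± 6.68 to 91.3 ± 20.7 (adjusted p = 0.0486), a call lost with the same scaling, without any 1 normoxic library and without hypoxia replicate 3, which took its log2 fold change from -0.37 to -0.17. The NCL value rested on transcripts with an expression-weighted length of 611 bases and on 1854 to 3803 estimated reads per library. It may therefore not stand for the full-length messenger RNA. Nucleophosmin (NPM1) was at 802 and 600 RPKM, with an SD of 224 in hypoxia (adjusted p = 0.0874). It passed without hypoxia replicate 2, where the log2 fold change of NPM1 was -0.75.

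RNA polymerase I, which transcribes the ribosomal RNA genes, showed lower messenger RNA of part of its machinery. Of 18 members, 9 were lowered and 0 raised (13 lowered adjusted over the list alone), with a median log2 fold change of -0.30 (camera, adjusted p = 0.00234; adjusted p = 0.108 with an estimated correlation). The largest subunit, POLR1A (ENSG00000068654, chromosome 2, 86020216 to 86106155), fell from 17.8 ± 0.874 to 11.1 ± 1.41 RPKM (log2 fold change -0.65, SE 0.09, adjusted p = 4.51e-04). POLR1F fell from 5.33 ± 0.210 to 3.38 ± 0.566, POLR1B from 16.6 ± 1.12 to 12.4 ± 2.16, a call lost without normoxia replicate 2, and the initiation factor RRN3, which overlaps PDXDC1 on the other strand, from 27.7 ± 1.12 to 22.1 ± 1.66. The activator UBTF was at 56.4 ± 1.06 and 55.9 ± 0.743, a log2 difference of -0.01 (adjusted p = 0.857). Of 27 members of the RNA polymerase III machinery 15 were lowered and 1 raised (15 and 1 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.0104; adjusted p = 0.143 with an estimated correlation). POLR3K fell from 12.5 ± 0.612 to 8.82 ± 0.108 and GTF3C6 from 41.2 ± 0.782 to 31.1 ± 6.01, while the polymerase III repressor MAF1 rose from 82.0 ± 2.29 to 93.9 ± 7.67. The polymerase III call was lost with a filter of at least 5 RPKM (adjusted p = 0.0712). It stayed with the GC trend removed, where the median was -0.17, and with GC and length trends removed, where it was -0.16. The number of lowered members was 10, 8 and 9 without normoxia replicate 1, 2 or 3, 8 with upper-quartile scaling and 4 with no filter.

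Part of the cytosolic ribosomal protein genes were slightly raised. Of 84 members 40 were raised and 2 lowered (45 and 2 adjusted over the list alone), with a median log2 fold change of 0.18 (camera, adjusted p = 1.61e-13; adjusted p = 0.363 with an estimated correlation, and 0.0521 with fry). RPL13A rose from 1143 ± 47.1 to 1558 ± 118 RPKM and RPL13 from 2682 ± 55.3 to 3508 ± 369. The lowered members were the paralogs RPS27L and RPL26L1. The number of raised members was 13, 21 and 23 without normoxia replicate 1, 2 or 3, 21 and 24 without hypoxia replicate 2 or 3, 60 and 62 with median-of-ratios and upper-quartile scaling and 6 with no filter on low values, and the median was 0.12 with libraries rescaled to equal sums and 0.10 with the length trend removed. The mean log2 level of biogenesis factors minus that of ribosomal proteins was -4.40 ± 0.04 in normoxia and -4.93 ± 0.09 in hypoxia, a difference of -0.53. It was lower in all 3 hypoxic than in all 3 normoxic libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow).

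Of mitochondrial ribosomal protein genes 38 of 78 were lowered and 2 raised (39 and 2 adjusted over the list alone), with a median of -0.19 (adjusted p = 7.00e-04; adjusted p = 0.622 with an estimated correlation). MRPL1 fell from 27.3 ± 1.58 to 18.5 ± 4.78 and MRPL42 from 21.4 ± 0.845 to 15.1 ± 2.22 RPKM, while MRPL17 and MRPL10 rose. The number of lowered members was 21 and 22 with median-of-ratios and upper-quartile scaling, 16 with no filter, and 24 and 21 without normoxia replicate 2 or 3. Translation factors went both ways, with 10 of 49 raised and 20 lowered (10 and 21 adjusted over the list alone; median -0.17, adjusted p = 0.216), and passed with fry (0.0152) and with no filter (0.0103). With median-of-ratios scaling 13 were lowered, and 5 were raised without normoxia replicate 1 or with no filter. The translation repressors EIF4EBP1 (log2 fold change 0.44) and PDCD4 rose, and EIF2B3 and the release factor ETF1 (69.1 ± 1.87 to 48.8 ± 4.54) fell. Among 20 snoRNA host genes 4 were raised and 1 lowered (3 and 1 adjusted over the list alone; median 0.04, adjusted p = 0.0765), and the sign of that median changed with libraries rescaled to equal sums, with the length trend removed and without normoxia replicate 3, and the median was 0.10 without hypoxia replicate 3. The list passed without hypoxia replicate 3 (adjusted p = 0.0109), without normoxia replicate 1 (0.0425) and with the filter of at least 5 RPKM (0.0379). SNHG32 rose from 109 ± 6.55 to 151 ± 7.54.

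**Figure D2:**
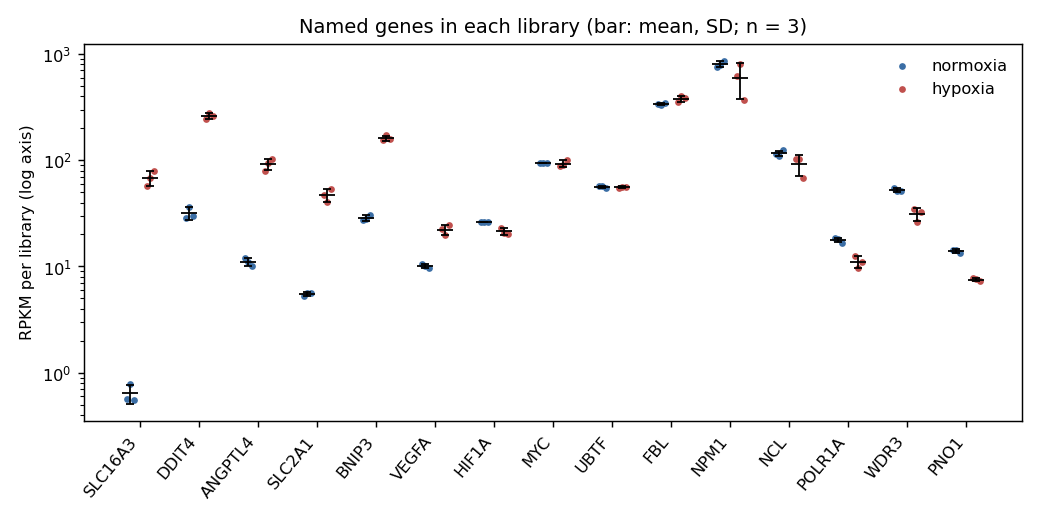
RPKM of 15 named genes in each of the 3 normoxic (blue) and 3 hypoxic (red) libraries on a log axis, with the mean and SD in black. SLC16A3 rose from 0.638 to 68.1 RPKM, and POLR1A, WDR3 and PNO1 were lower in all hypoxic libraries.

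Among genes of oxidative metabolism, 12 of 22 members of the tricarboxylic acid cycle were lowered and 2 raised (14 and 2 adjusted over the list alone), with a median of -0.21 (adjusted p = 0.00606; adjusted p = 0.143 with an estimated correlation). IDH3A fell from 35.6 ± 1.08 to 23.3 ± 2.17 RPKM and SUCLA2 from 42.9 ± 0.941 to 32.3 ± 1.56, while IDH2 rose from 65.7 ± 1.19 to 77.7 ± 5.24. With median-of-ratios scaling and without normoxia replicate 3 the number lowered was 8. Of 76 nuclear genes of the respiratory chain 26 were lowered and 1 raised, the same adjusted over the list alone (median -0.11, camera adjusted p = 0.0323, and 0.715 with an estimated correlation). This median differed from that of all tested genes by only -0.028. Cytochrome c (CYCS) fell from 91.1 ± 3.49 to 63.6 ± 9.32, and ATP5MC2 rose. That call was lost with median-of-ratios (adjusted p = 0.194) and upper-quartile scaling (0.172), the filter of at least 5 RPKM (0.130), the GC trend removed (0.0828), protein-coding transcripts only (0.158), ranks (0.0544) and fry (0.103). It was also lost without normoxia replicate 3 (0.106), hypoxia replicate 1 (0.453) or hypoxia replicate 3 (0.0771), and was stronger with the length trend removed (2.05e-07). The number lowered was 14, 13 and 11 without normoxia replicate 1, 2 or 3, 8 with median-of-ratios scaling, 9 with no filter and 42 with libraries rescaled to equal sums. Of 13 messenger RNAs from the mitochondrial genome 2 were lowered, also over the list alone, MT-ND2 (1286 ± 193 to 934 ± 114) and MT-ND1 (median -0.19, adjusted p = 0.243). The call depended on the setting: 7 were lowered without normoxia replicate 3 (adjusted p = 0.00214) and with the replicate number as a block (0.0139), and 4 with the length trend removed, where the list also passed. Without normoxia replicate 1 only 1 was lowered (median -0.05, adjusted p = 0.851), and none with the GC trend removed (median -0.06, adjusted p = 0.765) or with no filter. The mitochondrial ribosomal RNAs rose, MT-RNR1 from 111 ± 15.3 to 187 ± 36.2 and MT-RNR2 from 239 ± 38.4 to 316 ± 58.7 (adjusted p = 0.00139 and 0.0329), the latter a call lost without normoxia replicate 2 or 3 or hypoxia replicate 1.

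Part of the cell cycle and repair genes were lowered. Of 45 replication and G1/S genes 18 were lowered and 2 raised (21 and 2 adjusted over the list alone), with a median of -0.17 (adjusted p = 0.00234; adjusted p = 0.304 with an estimated correlation). POLE2 fell from 8.86 ± 0.515 to 6.09 ± 1.29 and DBF4 from 14.5 ± 0.366 to 10.4 ± 0.688 RPKM, while CDT1 and TK1 (133 ± 4.08 to 165 ± 14.1) rose. Of 40 G2/M genes 13 were lowered and 0 raised, also over the list alone (median -0.16, camera adjusted p = 0.0323, and 0.623 with an estimated correlation). Among those lowered were CDC25B (58.7 ± 0.683 to 40.4 ± 1.18) and MKI67. The G2/M median differed from that of all tested genes by -0.078. Of 24 genes of homologous recombination and the Fanconi pathway 13 were lowered and 0 raised, also over the list alone (median -0.24, adjusted p = 0.0104; adjusted p = 0.304 with an estimated correlation), among them NBN and XRCC2. With the trend of values on GC content removed, the G2/M and repair calls ended (adjusted p = 0.930 and 0.188). The G2/M call also ended with median-of-ratios (0.111) and upper-quartile scaling (0.103), with a filter of at least 5 RPKM (0.119), on ranks (0.0544), with fry (0.0521), and without normoxia replicate 3 (0.0777) or hypoxia replicate 3 (0.247, median -0.07). The numbers of lowered genes depended on the setting. Median-of-ratios scaling lowered 10 replication, 3 G2/M and 4 repair genes, and fits without a filter 10, 4 and 4. Without normoxia replicate 1, 2 or 3 they were 11, 13 and 11 for replication, 5, 5 and 4 for G2/M, and 5, 4 and 5 for repair.

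Stress programmes moved in different directions. Of 16 heat shock genes 13 were lowered and 1 raised (14 and 1 adjusted over the list alone), with a median of -0.37 (adjusted p = 5.23e-04; adjusted p = 0.152 with an estimated correlation). The chaperone HSPH1 fell from 69.0 ± 1.56 to 42.2 ± 3.69 RPKM and the cochaperone CHORDC1 from 47.6 ± 3.44 to 29.7 ± 2.43, while the small heat shock protein HSPB1 rose from 349 ± 15.6 to 534 ± 84.4. Of 22 endoplasmic reticulum chaperone and unfolded protein response genes 9 were raised and 1 lowered (10 and 1 adjusted over the list alone; median 0.20, adjusted p = 0.00234; adjusted p = 0.108 with an estimated correlation). PDIA4 rose from 43.1 ± 2.72 to 69.8 ± 5.44 and HSP90B1 from 206 ± 9.28 to 279 ± 38.9, and DNAJB11 fell. The number raised was 6 without normoxia replicate 3 and 5 with no filter. Targets of ATF4 and the integrated stress response went both ways, with 7 of 31 raised and 7 lowered (7 and 8 adjusted over the list alone; median -0.07, mean -0.003, test direction up, adjusted p = 0.597), and the sign of the median changed with median-of-ratios and upper-quartile scaling. The number lowered was 4 with either scaling and without normoxia replicate 2 or 3. STC2 rose from 59.4 ± 1.56 to 147 ± 5.24, and the amino acid transporter SLC38A2 fell from 109 ± 4.89 to 77.2 ± 7.81. Of 18 immediate early genes 7 were raised and 0 lowered, also over the list alone (median 0.14, adjusted p = 7.00e-04; adjusted p = 0.313 with an estimated correlation), led by KLF2 (12.1 ± 0.834 to 28.2 ± 4.04) and IER3. That median was 0.06 without hypoxia replicate 3 and with the GC trend removed, 0.22 without hypoxia replicate 1, 0.08 with libraries rescaled to equal sums and 0.23 with median-of-ratios scaling. Of 17 p53 targets 4 were raised and 4 lowered, also over the list alone (median -0.11, mean 0.03, test direction up, adjusted p = 0.561). Only 2 were lowered with either scaling and without any 1 normoxic library or hypoxia replicate 2, and the median was -0.04 without normoxia replicate 3. The cyclin-dependent kinase inhibitor CDKN1A rose from 2.27 ± 0.132 to 6.23 ± 0.962. Of 22 interferon-stimulated genes 2 were raised, IRF9 and IRF7, and 6 lowered, also over the list alone (median -0.07, adjusted p = 0.662), a median whose sign changed with median-of-ratios scaling. The number lowered was 4 with either scaling and without any 1 normoxic library, and the median was -0.13 without normoxia replicate 1.

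Of 23 collagens and collagen-modifying enzymes 13 were raised and 3 lowered, also over the list alone, with a median of 0.31 (adjusted p = 1.70e-07; adjusted p = 0.152 with an estimated correlation). The hydroxylases led: the lysyl hydroxylase PLOD2 rose from 1.22 ± 0.144 to 10.7 ± 0.895 RPKM and the prolyl hydroxylase P4HA2 from 11.6 ± 0.352 to 43.4 ± 2.47, while COL12A1 and COL4A2, which overlaps COL4A1 on the other strand, fell. Of 26 genes of epithelial-mesenchymal transition and invasion 8 were raised and 5 lowered, also over the list alone (median 0.02, adjusted p = 0.0235; adjusted p = 0.304 with an estimated correlation). The call ended on ranks (adjusted p = 0.107). The median was -0.04 with libraries rescaled to equal sums, 0.10 with median-of-ratios scaling and 0.007 without normoxia replicate 3. The largest member of this list by far was ANGPTL4, at 2.93. ANGPTL4, PLOD2 and P4HA2 are also in the list of HIF targets. So are SLC2A1, STC2, EGLN1, KDM3A, KDM4B and MXI1, named here as raised members of other lists, so those lists are not separate from it. The urokinase receptor PLAUR rose from 43.6 ± 1.04 to 66.7 ± 4.56, and tenascin C (TNC) and MET fell. Of 24 cholesterol synthesis genes 17 were lowered and 1 raised (18 and 1 adjusted over the list alone; median -0.32, adjusted p = 7.00e-04; adjusted p = 0.152 with an estimated correlation), with HMGCS1 falling from 17.9 ± 0.123 to 12.9 ± 1.49 and LSS from 46.4 ± 4.24 to 34.0 ± 3.33, and PMVK rising. With no filter 10 were lowered.

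The regulators of the response were less uniform. HIF1A fell from 26.2 ± 0.197 to 21.3 ± 1.47 RPKM (log2 fold change -0.29, SE 0.07, adjusted p = 0.00756), a call that ended with the GC trend removed, where it was -0.08 (adjusted p = 0.295). EPAS1, which encodes HIF2A, rose from 12.9 ± 0.497 to 14.9 ± 0.226 (adjusted p = 0.0411), a call lost on leaving out any single library. ARNT, the shared partner, was at 19.5 ± 1.21 and 18.7 ± 2.99 (adjusted p = 0.606). Of 11 HIF pathway components 2 were raised and 3 lowered (2 and 4 adjusted over the list alone, median -0.16, adjusted p = 0.651), and the oxygen sensor EGLN1 rose from 11.6 ± 0.659 to 18.1 ± 1.06. Without normoxia replicate 3 only 1 component was raised and 1 lowered. Of 21 chromatin dioxygenases that use 2-oxoglutarate 7 were raised and 5 lowered, also over the list alone (median -0.13, mean 0.06, test direction up, adjusted p = 0.168). This list passed with the length trend removed (adjusted p = 0.0210, 9 raised and 3 lowered) and without hypoxia replicate 2 (0.0410), where the median was -0.02. With median-of-ratios or upper-quartile scaling 8 were raised and 1 lowered, and without normoxia replicate 1 or 2 also only 1 was lowered. With limma-voom 9 were lowered, and the median turned positive with the GC trend, the length trend or both removed. KDM4B rose from 5.61 ± 0.107 to 11.8 ± 0.950 and KDM3A from 15.2 ± 0.472 to 27.9 ± 1.73. MYC was at 94.6 ± 0.497 and 93.0 ± 6.51 (adjusted p = 0.756). Of 10 MYC network genes 4 were raised and 2 lowered, also over the list alone (median 0.04, adjusted p = 0.105), with the MYC antagonist MXI1 rising from 2.45 ± 0.358 to 5.22 ± 0.413 and MLXIP falling, and the sign of that median changed in 6 settings, among them libraries rescaled to equal sums. The MYC network and HIF pathway lists passed with fry (adjusted p = 0.0113 and 0.0302).

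The 10 largest decreases of well-expressed genes lay mostly at low GC content, where fold changes were lower. All but ABCF2-H2BK1 (52.3%) were below the median of tested genes, 50.5%, from EREG at 36.3% to PEG10 at 47.5%. ZMPSTE24 and VRK1 were lowest in hypoxia replicate 3 (7.18 and 4.61 RPKM), which had the steepest trend of values on GC content. These decreases were smaller than the largest increases. Besides PNO1 and WDR3, they were the lamin-processing protease ZMPSTE24 (18.9 ± 1.89 to 10.3 ± 2.81 RPKM), the EGF receptor ligand EREG (7.58 ± 0.321 to 3.95 ± 0.422), PEG10, which overlaps SGCE (40.5 ± 0.561 to 23.3 ± 3.02), the arginine methyltransferase PRMT3 (21.1 ± 0.901 to 12.2 ± 1.06), osteopontin (SPP1, 7.93 ± 0.501 to 4.35 ± 0.266), CTNNAL1 (log2 fold change -0.73), ABCF2-H2BK1, which shares exons with ABCF2 and is uncertain, and the kinase VRK1 (11.9 ± 1.41 to 7.04 ± 2.38).

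Signs of library composition moved with the groups. Of 10 RNAs that mostly lack a poly(A) tail 4 were raised and 1, the histone gene H2BC12, was lowered, also over the list alone (median 0.13, adjusted p = 0.00125; adjusted p = 0.108 with an estimated correlation), among them RN7SK, which shares its position with a copy listed as 7SK (2.02 ± 0.133 to 9.64 ± 2.63 RPKM) and RMRP (0.976 ± 0.156 to 5.40 ± 1.16). The call ended with GC and length trends removed (camera, adjusted p = 0.0664), and the median was 0.06 without hypoxia replicate 2 and 0.19 without hypoxia replicate 3. It also ended with protein-coding transcripts only (0.450, 6 tested). That limit leaves out the 4 raised RNAs, which are noncoding, so the loss was fixed in advance and shows nothing about them. The 50 most abundant genes held 13.3% ± 0.121 of reads in normoxia and 16.4% ± 0.572 in hypoxia. Fold changes followed the GC content and length of transcripts across genes, with Spearman's rho 0.42 and -0.23 over 11884 genes, which are not independent replicates. The GC trend differed between hypoxic libraries: per 10 points of GC content the log2 value changed by 0.159 in hypoxia replicate 3, which had the fewest reads, by 0.0432 in replicate 2 and by -0.00433 in replicate 1, against -0.0521, -0.0526 and -0.0931 in normoxia. Of 10 groups of equal size, the one with the lowest GC content had a median log2 fold change of -0.24 and the one with the highest 0.09.

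**Figure D3:**
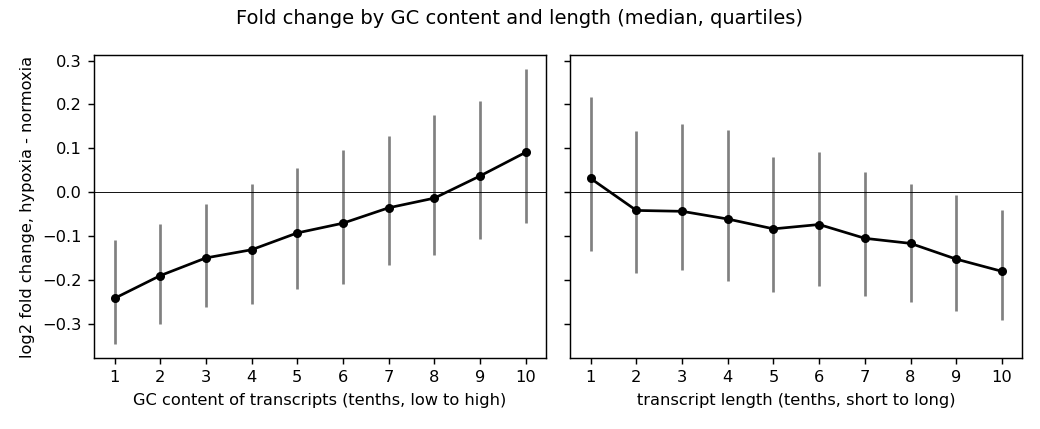
Median log2 fold change, hypoxia against normoxia, with quartiles (bars), of tested genes in 10 groups of equal size by GC content (left) and by length (right) of their transcripts. Medians go from -0.24 to 0.09 with GC content and from 0.03 to -0.18 with length.

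Most epithelial markers were near 0 although the line comes from a breast carcinoma: EPCAM, CDH1 and KRT8 averaged 0.0304, 0.0139 and 0.0284 RPKM in normoxia, and KRT5 and KRT14 stayed at 0.0679 or less in both groups. Of the fibroblast markers COL1A1 and COL1A2 were at 257 and 226 RPKM, while COL3A1, LUM, PDGFRB, POSTN and THY1 were at 0.0715 or less. None of the basal epithelial and endothelial markers was high enough to be tested; the highest were ITGB4 at 0.133 ± 0.0280 and KDR at 0.137 ± 0.0344 RPKM in normoxia. Of luminal markers 2 were tested and GATA3 was lowered (4.93 ± 0.219 to 3.77 ± 0.826). Of fibroblast markers 4 were tested, with COL1A1 (257 ± 21.2 to 390 ± 26.9), COL1A2 and FAP raised and PDGFRA lowered. Of leukocyte markers 2 were tested and CD68, a lysosomal protein also made outside leukocytes, was raised (46.7 ± 1.39 to 77.2 ± 3.60).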

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

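Transcripts that could not be joined to a gene were kept out of every comparison of genes, and they too differed between the groups. Among 1754 such transcripts above the same limit, 31 were raised in hypoxia above their normoxic level and 12 were lowered (limma, adjusted p under 0.05). The transcript ENST00000674765 rose from 3.33 ± 0.281 to 26.4 ± 5.85 RPKM and ENST00000652618 from 0.444 ± 0.332 to 7.42 ± 1.23 (SD over 3 libraries), and ENST00000677196 and ENST00000676913 fell. Their genes are not named here, so no explanation was tested.

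The other splits of the libraries, the scaling and the non-polyadenylated RNAs below were tests chosen only after the results were seen; those on GC content and length were written down before theirs. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 4379 genes, 1478 raised and 2901 lowered, with 108 changed at least 2-fold, and was the 1 split that reached each number. The highest other split gave 0. Every other split mixes normoxic and hypoxic libraries, so the difference between the groups enters its spread and hides calls. The contrast in counts is therefore no support for the calls. For the absolute list medians the real value and the highest other were 0.39 and 0.16 for ribosome biogenesis factors, 0.30 and 0.13 for the polymerase I machinery, 0.18 and 0.14 for cytosolic ribosomal proteins, and 1.26 and 0.48 for HIF targets.

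For the lower level of ribosome biogenesis factors (median log2 fold change -0.39), the values argue against GC content and length bias as the whole cause. The list was near typical in both. Its median GC content was 49.3% against 50.5% over all tested genes, and its median length 2264 against 2369 bases. Tested genes with GC content of 47.8% to 50.5% had a median log2 fold change of -0.09. With GC and length trends removed per library the median was -0.30 (spread 0.03, camera adjusted p = 6.51e-18, and without that removal 0.108 with an estimated correlation). That was below the bound of -0.2, set before this fit, which was itself chosen after seeing the data. A list of near-typical GC content and length could move only a little, so passing the bound adds little. With median-of-ratios scaling, which discounts a few abundant genes that take more reads in hypoxia, the list median was also -0.30 (spread 0.04). That scaling moves all genes of a library alike, here by a median of 0.073. The median of all tested genes was already known to be -0.085, so the list median was bound to stay low. The result shows only that the list lay below the typical gene. A biological response to low oxygen stays open as a hypothesis.

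The small increase of cytosolic ribosomal proteins (median 0.18) is not settled. These transcripts are short, with a median of 738 bases against 2369 over all tested genes, and shorter genes had higher fold changes. With the length trend removed the median was 0.10 (spread 0.03, adjusted p = 3.19e-06; without that removal adjusted p = 0.363 with an estimated correlation). That lies just above the bound of 0.1 set beforehand, which alone would have ruled out length bias as the whole cause. The margin is less than the spread, an allowance added after the value was seen, and with it length bias and a biological increase cannot be told apart.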

How the results depend on the processing

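Libraries rescaled to equal sums, limma-voom, the GC and length corrections and the limit to protein-coding transcripts were chosen after seeing the data. The median log2 fold changes of HIF targets, ribosome biogenesis factors, the polymerase I machinery and cytosolic ribosomal proteins kept their direction under all alternatives run, and passed camera at the preset correlation in all refits. With an estimated correlation only HIF targets kept their call in camera (adjusted p = 0.0215). Lists without a call at the preset correlation gained none. Of 28 lists 18 lost their call. Among them were biogenesis factors (-0.39, adjusted p = 0.108), polymerase I (-0.30, adjusted p = 0.108) and ribosomal proteins (0.18, adjusted p = 0.363). The estimated correlation was 0.60 for ribosomal proteins but -0.0084 for polymerase I, below the preset 0.01. Correlated members therefore do not account for every loss, and the cause was not tested. With fry the ribosomal protein call ended (0.18, adjusted p = 0.0521). Genes lowered were 1422 with median-of-ratios and 1467 with upper-quartile scaling. These scalings moved log2 fold changes up by a median of 0.073 and 0.069, which by itself leaves fewer genes lowered. Without a filter 26409 genes were tested, genes changed in hypoxia were 2436, and 1367 were lowered. Of 115 named genes, 36 lost their call without a filter, 9 with the GC trend removed and 8 with median-of-ratios scaling. Without normoxia replicate 1, 2 or 3, 15, 16 and 13 named genes lost it. Genes changed at least 2-fold were 194 with a pseudocount of 0.1 and 210 with limma-voom, which shrink weak genes less. The test against a 1.5-fold change called 113 genes, 113 raised and 0 lowered (at an unadjusted p under 0.05 with no fold limit, 5765 genes). Leaving out single libraries gave 2549 to 4370 genes changed and 1522 to 2852 lowered. Lowered genes were 1754, 1621 and 1522 without normoxia replicate 1, 2 or 3, but 2852, 2827 and 2731 without hypoxia replicate 1, 2 or 3. Each fit lost 1 library, so lower power from fewer samples does not account for that difference. The median SD of genes within a group was 0.061 in normoxia and 0.111 in hypoxia (log2 scale). Whether this unequal spread is the cause was not tested. The median log2 fold change of epithelial-mesenchymal transition and invasion was -0.0400 with libraries rescaled to equal sums. That rescaling moved log2 fold changes by a median of -0.059, and the list median was 0.02 without it. The median log2 fold change of 2-oxoglutarate-dependent chromatin dioxygenases was 0.0611 with the length trend removed, 0.0247 with the GC trend removed and 0.0781 with both removed. The cause of the changes in the dioxygenase list was not tested.

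With the replicate block genes changed in hypoxia were 4129, 1465 raised and 2664 lowered, 3917 of them shared with the calls without it. Same-numbered libraries did not deviate together across genes (correlations 0.09, 0.03 and -0.23), and not every library correlated best with its own number. With 3 libraries per group these correlations cannot exclude a culture or day shared by equal numbers. For messenger RNAs from the mitochondrial genome the block mattered, with 7 lowered (camera, adjusted p = 0.0139) against 2 without it (0.243). The table holds RPKM rather than counts, so the planned edgeR and DESeq2 fits were not run, and only limma-voom was fitted to estimated reads. Scaling by total counts is the RPKM as deposited. Depth of 44.0 to 50.9 M reads limits only weakly expressed genes such as CA9.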

Other observations

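A pair of lincRNA genes on chromosome 21 were singled out after their values were seen. FP236383.3 (8437629 to 8438551, minus strand, GRCh38) rose from 293 ± 58.4 to 943 ± 182 RPKM (SD over 3 libraries each; limma, adjusted p = 1.72e-05), and its copy FP236383.2 (8393419 to 8394341) from 4.20 ± 0.369 to 12.3 ± 2.62. The sequence opposite to each holds a match to a 20-base primer in common use for 18S ribosomal RNA, so reads counted there can come from 18S RNA, and the copies may share them. The small RNAs RN7SL1 and RN7SL2 of the signal recognition particle rose as well, from 9.56 ± 2.35 to 25.5 ± 3.19 for RN7SL1 and 3.03-fold for RN7SL2. BCYRN1, another RNA polymerase III product, fell from 27.8 ± 5.84 to 17.3 ± 5.80 (adjusted p = 0.0236). The values are no measure of ribosomal RNA synthesis.

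The origin of the reads in these lincRNA genes was not tested; a candidate explanation for their rise, examined only after it was seen, is that hypoxic libraries held more RNA without a poly(A) tail. RMRP, RN7SK, RN7SL1 and RN7SL2, made by RNA polymerase III, had a median log2 ratio of means of 1.93, against 1.69 for FP236383.3. BCYRN1, left out of that group, went the other way with a log2 ratio of -0.68, so not all polymerase III products rose. The 6 histone genes, whose messenger RNAs mostly lack the tail too, had a median of 0.01. Histone output can fall with replication and tailed forms exist, so this decides nothing, and carry-over of untailed RNA and a higher content of these RNAs per cell cannot be told apart, since no table gives RNA per cell.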
